A study of Oryza sativa with 20 samples.

How the data were processed

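The intensity values were analysed as deposited by the authors: a linear relative intensity for each of 57381 probe sets on 20 Affymetrix rice arrays. The submitters' processing notes name GCOS 1.3. The values themselves show that the 75th percentile of every array is 1, that the lowest value is 0.01 (8 probe sets), and that no log or centring was applied. Which program set these is not given in the sources used here. No detection calls were used here. Per the labels, 500 ng of total RNA was labelled per array. All 20 columns were matched to samples (0 unmapped), and no sample was left out.

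Values under 0.128, the 20th percentile of the table, were raised to it and log2 was taken, with no further normalization. Between 0.169% and 7.32% of an array lay at that floor among tested probe sets. The 187 control probe sets were left out, and probe sets above the array median on at least 2 arrays were kept, 35470 in number. Group means of the 7 groups were fitted with limma 3.58.1 in R 4.3.3 (13 residual degrees of freedom), with moderated variances and a trend on the mean. Benjamini-Hochberg adjustment was made within each comparison, and a probe set was called at an adjusted p under 0.05. Pistils were compared with both unpollinated tissues, a call needed both comparisons in the same direction, and the value given is the smaller of the 2 changes. Fold changes are ratios of geometric means, that is differences of log2 group means, so they differ from ratios of the printed arithmetic means. Where an array of the lower group lies at the floor the fold change is a lower bound, written as at least where 2 or more arrays do. Errors on log2 changes are standard errors from the fit, and errors on intensities are standard deviations. Random draws used fixed seeds.

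The annotation table gives 1 gene for 22436 probe sets, several for 95 and none for 34850. Of the tested probe sets 19579 had 1 gene, and 2274 tested genes had a symbol other than a locus number. Genes without a symbol are counted but not named. Named genes follow a rule fixed before the data were examined. For each of the first 6 comparisons it takes the 6 largest rises and the 6 largest falls among called genes whose arrays do not overlap (not asked of the interaction), and 2 genes per list. Against both tissues it takes 4 rises, 4 falls and 1 gene per list. The rule asked for a product name. The naming tables hold none, so a symbol was asked for instead. It gave 327 pairs of gene and comparison, and a part of them is printed.

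Gene lists were tested with limma's cameraPR at a preset correlation of 0.01, and with camera at a correlation estimated from the arrays. Each gene was represented by its tested probe set with the highest mean (16263 genes), and adjustment was over the 25 lists of at least 5 genes, of 29 in all. The lists had been planned as patterns on product names. They were rewritten as symbol patterns after the table's columns, array summaries and correlations had been seen, but before any test was run. Translated, some of them widened, were expansins, wall enzymes (cellulose and hemicellulose added to pectin), actin cytoskeleton (RAC genes added), jasmonate, ethylene (ERF and DREB added), auxin, gibberellin, cytokinin, WRKY (NAC and MYB added), calcium signalling (pumps and exchangers added), heat shock, redox enzymes, defence proteins, cell cycle and replication, ribosome (translation factors added) and photosynthesis. Also translated were sucrose and starch, seed storage proteins (planned as a single list with the former), water and sugar transport, carpel and ovule identity, tapetum and anther wall, stamen and lodicule, and nucellus and early endosperm. Added without a planned counterpart were kinesins and tubulins, abscisic acid, ion transport, MADS, HOX and YABBY factors, small RNA and chromatin, and the group-1 pollen allergen beta-expansins. Lists of pollen-named genes, ROP and RALF signalling, histones, lipid transfer and cuticle, and pollen MADS and sperm genes had been planned and are not analysed here.

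Alternatives fixed beforehand were quantile normalization, median centring, no filter, a filter at the 75th percentile, no floor, a floor at the 40th percentile, leaving out probe sets with cross-hybridising suffixes, variances without a trend, array weights, a fit of only the groups compared, the replicate number as a block, a 2-fold minimum, and each array left out in turn. Scaling on the 9103 probe sets bright on every array was added after seeing that array medians differ. The pipeline was tested on simulated data with 100 probe sets changed 2-fold and 100 changed 4-fold per comparison. Each simulated probe set had the same spread in all groups, whereas the real stigma groups varied more than the pistil groups. Recovery in the stigma may therefore be overstated. In the 5-min stigma comparison 36 of 100 changed 2-fold and 90 of 100 changed 4-fold were recovered, in the 5-min ovary comparison 43 and 95, and in the interaction 6 and 62. In the comparison of pistils at 5 to 7 h with 40 to 50 min, the only one simulated for lists, a list moved by 0.5 was called and 0 of the other lists were. Simulated probe sets varied independently of each other, so this does not test list calls that arise from correlated genes. Regrouped real arrays of that comparison gave up to 13 lists, though such groupings keep part of the real difference.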

Results

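Transcript levels were measured in rice pistils around pollination on 20 Affymetrix rice arrays, each hybridised with RNA from 1 sample of field-grown flowers. The arrays fall in 7 groups: unpollinated stigma (n = 3), unpollinated ovary (n = 3), stigma 5 min after pollination (n = 2), ovary 5 min after pollination (n = 3), and whole pistils, stigma and ovary together, at 15 to 25 min, 40 to 50 min and 5 to 7 h after pollination (n = 3 each). Per the labels, samples taken after pollination include the pollen grains, so a gene that is higher in them can be read from pollen, pollen tube or pistil RNA. The values are relative intensities in which the 75th percentile of every array is 1. Array medians ran from 0.195 to 0.377, and the number of arrays limits the precision. Arrays of a group correlated at r = 0.937 or more across 35470 tested probe sets, and no pair held identical values. The first principal component took 38.7% of the variance, the second 19.7%. The labels call the replicates biological but do not say whether they came from separate plants or days, so p-values measure only the spread between these samples, part of which can be technical. Gene names are those of the annotation table, no genome was used, and no coordinates are given. Counts are of probe sets unless genes are named, and fold changes are ratios of geometric means, so they differ from ratios of the mean intensities.

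**Figure D1:**
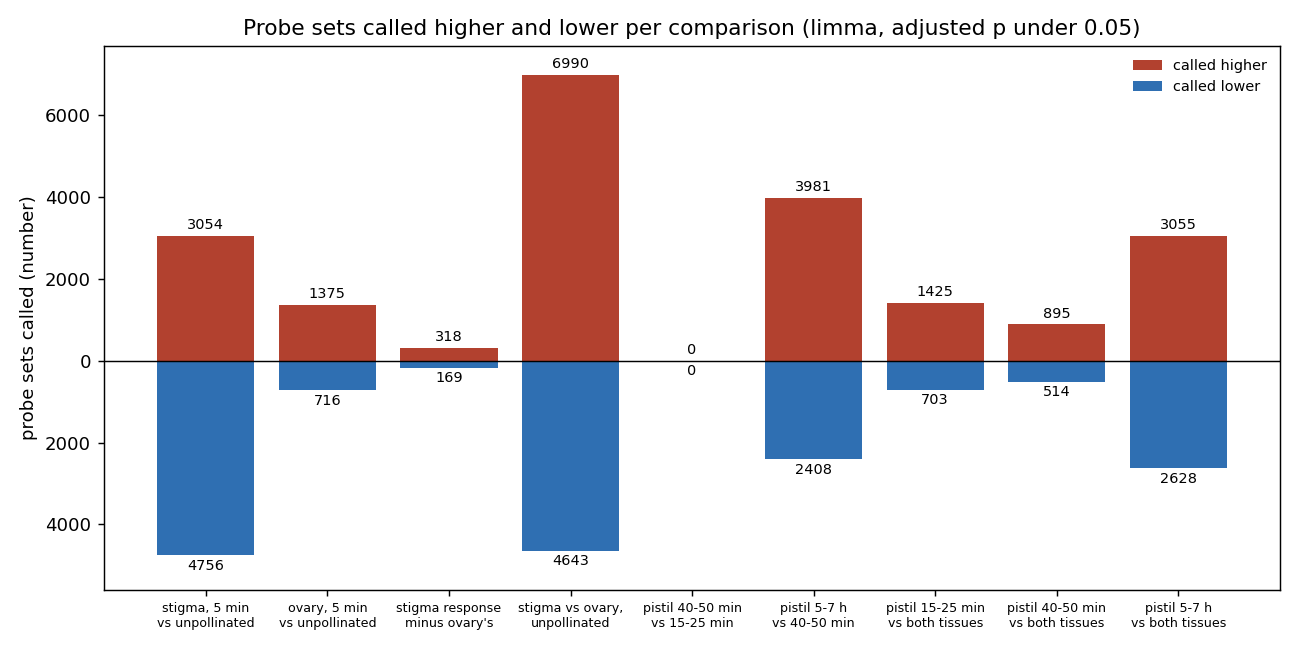
Number of probe sets called higher (bars above 0) and lower (bars below 0) in each of the 9 comparisons, from limma at an adjusted p under 0.05 over 35470 probe sets. Stigma and ovary before pollination differ at the largest number (6990 higher and 4643 lower in the stigma), and the pistils at 40 to 50 min against 15 to 25 min at none.

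The comparison of the stigma 5 min after pollination with the unpollinated stigma asks what the pollinated stigma, with its pollen, holds that the stigma before did not. ML (LOC4326471) rose from a mean relative intensity of 1.17 ± 1.64 (SD, n = 3) to 118 ± 39.9 (SD, n = 2), a log2 fold change of 7.82 ± 1.11 (SE). A chitinase (LOC4342115), an enzyme that cuts chitin, rose 120-fold, from 0.212 ± 0.117 to 25.6 ± 3.47. The metallothionein MT1B (83.6-fold), ASMT, which methylates acetylserotonin in melatonin synthesis (69.1-fold), the homeodomain-leucine zipper factor HOX12 (68.3-fold) and the dehydrin RAB16B (62.9-fold) followed, with log2 errors between 0.55 and 0.88. Falls were smaller. GH3.1, which conjugates auxin to amino acids, fell by 2.48 on the log2 scale (SE 0.39, n = 2 and 3), LOGL6, which releases active cytokinin, by a fitted log2 change of -2.28 (SE 0.37), and the mannan synthase gene CSLA1 by -2.05 (SE 0.39). Both arrays of the pollinated stigma lay beyond all 3 arrays of the unpollinated stigma for each of these genes, as the rule for naming them required.

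In total 3054 probe sets were higher and 4756 lower in the pollinated stigma, of which 2354 and 798 changed at least 2-fold. Median centring, array weights and a fit of only the groups compared each gave fewer calls, the last by far the fewest, as given below with the other settings. The balance of higher and lower depends on the scaling: with arrays scaled on 9103 probe sets that were bright on every array, 4172 were higher and 1831 lower. That scaling moved the median of all probe sets by 0.23 on the log2 scale, and centring on array medians moved it by -0.14. Without 5-min stigma replicate 2 the number called was 2968 instead of 7810.

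Genes of defence and of transport rose as groups in the pollinated stigma, and these 3 lists kept their call with an estimated correlation. Of 25 defence proteins 7 rose and 2 fell (7 and 2 adjusted over the list alone), with an adjusted p of 8e-07, and adjusted p = 0.0343 with an estimated correlation. Besides the chitinase named above, the chitinase Cht-3 rose 47.3-fold (log2 5.56 ± 0.37, SE). Among 36 water and sugar transporters 14 rose and 1 fell (16 and 1 adjusted over the list alone, adjusted p = 8e-07, adjusted p = 0.0487 with an estimated correlation). OsSWEET5, a sugar exporter, rose from 0.83 ± 0.454 to 20.1 ± 4.99, 27.2-fold, and the monosaccharide transporter MST3 rose 21.7-fold. Of 66 ion transporters 15 rose and 5 fell (15 and 5 adjusted over the list alone, adjusted p = 0.00229, adjusted p = 0.0487 with an estimated correlation). YSL7, of a family that moves chelated metals, rose 33.5-fold, and the phosphate transporter OsPht1;8, at the floor on 3 of 3 unpollinated stigma arrays, rose at least 21.6-fold.

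Lists of signalling and regulatory genes rose with the preset correlation and lost their call with an estimated one. Of 20 WRKY, NAC and MYB factors 10 rose and 0 fell (10 and 1 adjusted over the list alone, adjusted p = 0.000204, adjusted p = 0.198 with an estimated correlation), among them OsWRKY71 (14.8-fold) and MYB45 (8.4-fold). Calcium signalling had 27 of 83 genes higher and 12 lower (31 and 13 adjusted over the list alone, adjusted p = 0.00155, adjusted p = 0.301 with an estimated correlation). Its calcium-dependent kinases CPK29 and CPK2 rose 26.8-fold and 21.9-fold. Of 31 jasmonate genes 9 rose and 4 fell (16 and 5 adjusted over the list alone, adjusted p = 0.00261, adjusted p = 0.301 with an estimated correlation). The repressor gene JAZ8 rose by 4.50 ± 0.94 (log2, SE), a call that ended without 5-min stigma replicate 2 (3.20). In the abscisic acid list 20 of 69 genes rose and 6 fell (22 and 7 adjusted over the list alone, adjusted p = 0.00121, adjusted p = 0.301 with an estimated correlation), with the phosphatases OsPP2C59 (12.4-fold) and PP2C68 (7.24-fold). The abscisic acid and calcium lists lost their call without 5-min stigma replicate 1, at medians of 0.20 and 0.14.

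Cell wall lists rose as well, at the preset correlation only. Of 25 expansins, proteins that loosen the wall, 9 rose and 2 fell (9 and 3 adjusted over the list alone, adjusted p = 0.019, adjusted p = 0.198 with an estimated correlation). EXPB9, a beta-expansin of the group-1 pollen allergens, went from 3.52 ± 1.05 to 64.3 ± 2.51, and the other member of that pair, EXPB10, rose by 1.76 ± 0.41 (log2, SE), a call lost without 5-min stigma replicate 1 (2.46-fold). EXP32 rose 18.1-fold. Among 37 pectin, cellulose and hemicellulose enzymes 10 rose and 3 fell (10 and 3 adjusted over the list alone, adjusted p = 0.0251, adjusted p = 0.268 with an estimated correlation), including the endoglucanases GLU15 (22.2-fold) and GLU12 (9.61-fold). Both lists lost their call when arrays were scaled on always bright probe sets and without 5-min stigma replicate 1 (medians 0.49 and 0.19). A filter at the 75th percentile ended both as well, and no filter ended the wall enzyme call.

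Ribosome and translation genes fell together. Of 33 genes 27 fell and 0 rose (29 and 0 adjusted over the list alone), at a median log2 change of -0.73 (adjusted p = 8e-07, adjusted p = 0.315 with an estimated correlation), and RPS4 fell by 0.94 (SE 0.18). Of 38 small RNA and chromatin genes 2 rose and 14 fell (2 and 16 adjusted over the list alone, adjusted p = 0.0408, adjusted p = 0.438 with an estimated correlation), AGO14 by a log2 change of -1.73. That list lost its call without unpollinated stigma replicate 2 (median -0.33), without 5-min stigma replicate 2 (-0.29), under quantile and bright-probe scaling, and with a filter at the 75th percentile.

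The remaining lists did not pass in the stigma, though single members did. Actin cytoskeleton genes had 7 of 39 higher and 4 lower (adjusted p = 0.114), with the actin-depolymerizing factors ADF1 and ADF9 up 9.18-fold and 8.81-fold. Heat shock genes had 6 of 43 higher and 1 lower (4 and 1 adjusted over the list alone, adjusted p = 0.0811), with HSF23 up 5.25-fold. Auxin genes had 4 of 55 higher and 17 lower (4 and 18 adjusted over the list alone, adjusted p = 0.248), with ARF15 up 5.12-fold. Cell cycle genes had 2 of 62 higher and 17 lower (adjusted p = 0.127), among them CYCD5-1 with a log2 change of -1.74. Kinesins and tubulins had 1 of 43 higher and 9 lower (adjusted p = 0.419), TUB2 falling by 1.28. Cytokinin genes had 4 of 30 higher and 9 lower (adjusted p = 0.96; median and mean 0.01, tested downward), with LOGL3 up 5.39-fold. Redox enzymes had 8 of 60 higher and 7 lower (8 and 11 adjusted over the list alone, adjusted p = 0.96; median -0.15, mean 0.02), and OsTrx20 rose 10.2-fold. Sucrose and starch genes had 5 of 32 higher and 4 lower (6 and 6 adjusted over the list alone, adjusted p = 0.346; median -0.12, mean 0.20), with the alpha-amylases amy2A and AMY3D up 20.4-fold and 7.24-fold. MADS, HOX and YABBY factors had 8 of 60 higher and 11 lower (11 and 13 adjusted over the list alone, adjusted p = 0.96; median -0.10, mean 0.16), and HOX24 rose 17.2-fold. Ethylene genes had 2 of 17 higher and 3 lower (adjusted p = 0.96; median -0.02, mean 0.08), gibberellin genes 1 of 14 higher and 3 lower (adjusted p = 0.996), photosynthesis genes 0 of 17 higher and 3 lower (adjusted p = 0.96) and seed storage proteins 2 of 7 higher and 0 lower (adjusted p = 0.374). The 7 carpel and ovule identity genes split 1 higher and 2 lower (1 and 3 adjusted over the list alone, adjusted p = 0.96; median 0.12, mean -0.04). Markers of tapetum and anther wall (GAMYB, EAT1 and PTC1) and of stamen and lodicule (MADS16) did not pass, at log2 changes of 0.32, 0.54, -0.32 and 0.08, nor did MADS29 and nf-yb1 of nucellus and early endosperm, at 1.51 and 0.09 (1 higher adjusted over the list alone).

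**Figure D2:**
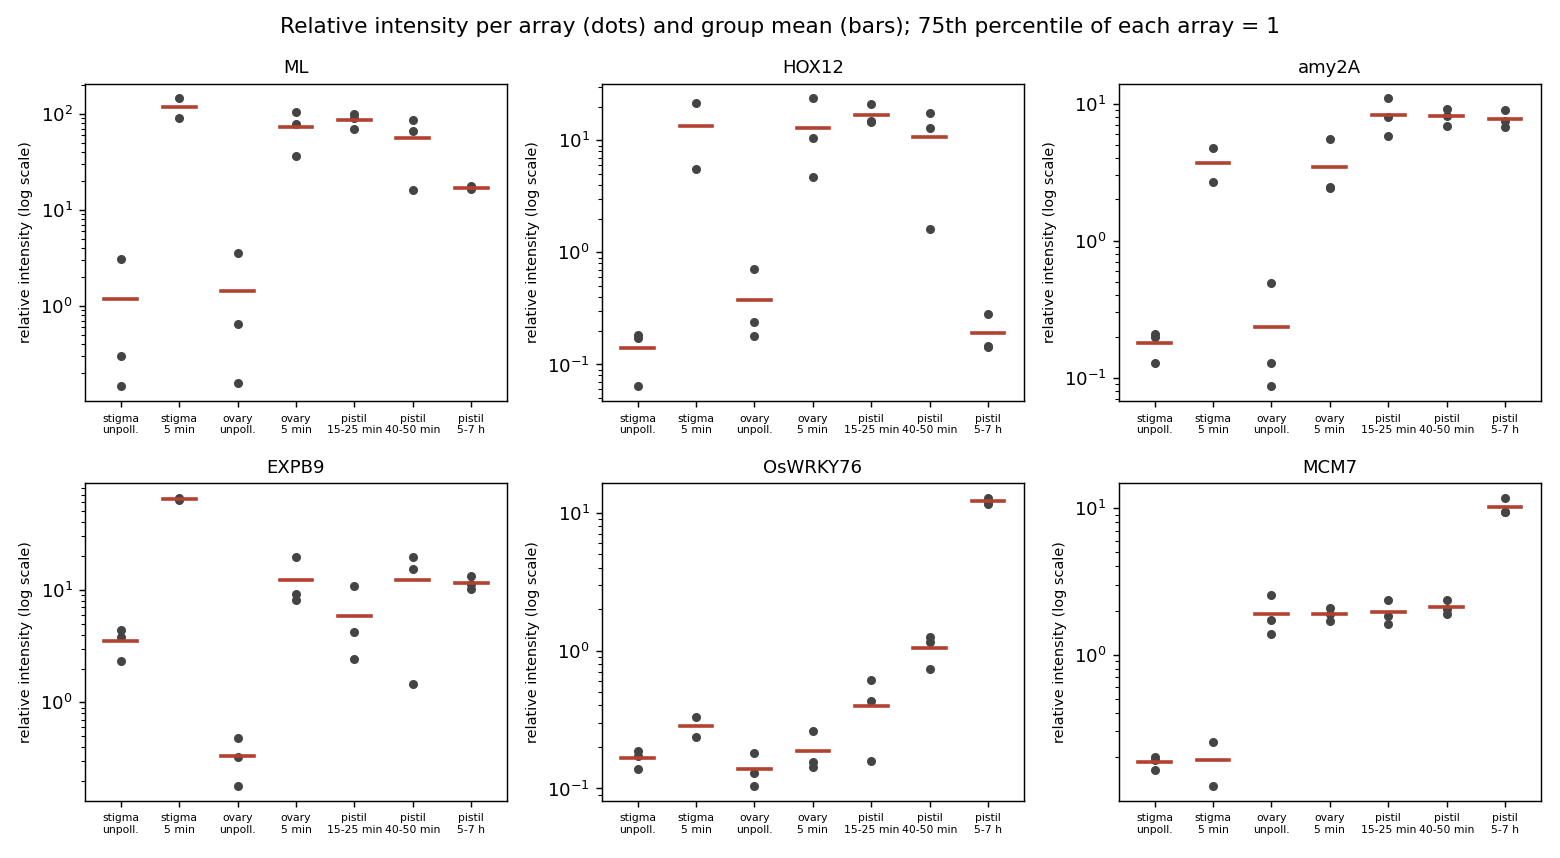
Relative intensity (log axis; 75th percentile of each array = 1) of ML, HOX12, amy2A, EXPB9, OsWRKY76 and MCM7 in the 7 groups, each dot an array and each red bar a group mean. ML and HOX12 rise in stigma and ovary by 5 min, HOX12 is back at 0.191 by 5 to 7 h, and OsWRKY76 and MCM7 reach 12.1 and 10.2 at 5 to 7 h.

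The ovary was compared with the unpollinated ovary in the same way, to ask what reaches or changes in the ovary within 5 min. ML rose from 1.43 ± 1.81 to 73.3 ± 34.1 (SD, n = 3 each), 95.1-fold. PBZ1, a defence protein of the PR10 family, rose 69.2-fold from 0.135 ± 0.00679 to 9.70 ± 3.55, ASMT at least 59.5-fold, the chitinase LOC4342115 53.9-fold, ERR26 39.1-fold and EXPB9 37.0-fold. The peroxidase gene PRX112 fell by 1.94 on the log2 scale (SE 0.32, n = 3) and BC1L2, of a family with roles in cellulose deposition, by a log2 change of -1.49 (SE 0.26). For each of these genes the 3 arrays of one group lay apart from the 3 of the other, a separation that chance gives 10% of genes in each such comparison. The rule for naming the largest changes required it, so it adds no evidence for them.

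In the ovary 1375 probe sets were higher and 716 lower, 1102 and 131 of them by at least 2-fold. Centring on array medians left 882 higher and 238 lower, and scaling on bright probe sets gave 1530 and 477. The number called, 2091, was 787 without 5-min ovary replicate 3, 792 without unpollinated ovary replicate 3 and 1023 without 5-min ovary replicate 1.

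Defence proteins rose most clearly in the ovary. Of 25 genes 8 rose and 0 fell (12 and 0 adjusted over the list alone, adjusted p = 1.33e-11), the 1 list in the ovary that kept its call, at adjusted p = 0.00521 with an estimated correlation. Jasmonate genes had 6 of 31 higher and 1 lower (14 and 2 adjusted over the list alone, adjusted p = 1.91e-05, adjusted p = 0.128 with an estimated correlation), and the oxophytodienoate reductase gene OPR1 rose 5.61-fold. Calcium signalling had 12 of 83 genes higher and 0 lower (15 and 0 adjusted over the list alone, adjusted p = 0.000102, adjusted p = 0.128 with an estimated correlation). CPK29 rose 9.65-fold, and CPK2, at the floor on 3 of 3 unpollinated ovary arrays, at least 7.88-fold. WRKY, NAC and MYB factors had 5 of 20 genes higher and 0 lower (7 and 0 adjusted over the list alone, adjusted p = 0.000155, adjusted p = 0.128 with an estimated correlation). Water and sugar transporters had 5 of 36 genes higher and 0 lower (5 and 1 adjusted over the list alone, adjusted p = 0.00044, adjusted p = 0.128 with an estimated correlation). OsSWEET5 rose from 0.132 ± 0.0396 to 3.65 ± 2.29, 22.6-fold, and OsSWEET15 9.06-fold. Ion transporters had 11 of 66 genes higher and 1 lower (11 and 1 adjusted over the list alone, adjusted p = 0.00576, adjusted p = 0.128 with an estimated correlation), with OsPht1;8 up at least 15.3-fold and YSL7 8.99-fold.

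Heat shock genes had 6 of 43 higher and 1 lower in the ovary (8 and 2 adjusted over the list alone, adjusted p = 0.00206, adjusted p = 0.311 with an estimated correlation), and the small heat shock protein gene HSP16.0 rose 7.63-fold. Expansins had 4 of 25 higher and 1 lower (6 and 1 adjusted over the list alone, adjusted p = 0.0189, adjusted p = 0.128 with an estimated correlation), with EXP32 up 8.82-fold. The expansin call ended without unpollinated ovary replicate 1 (median 0.18) or 5-min ovary replicate 2 (0.23). Shifted downward were the cell cycle list, with 1 of 62 genes higher and 2 lower (1 and 3 adjusted over the list alone; median -0.21, adjusted p = 0.0123, adjusted p = 0.211 with an estimated correlation), and the ribosome list, with 0 of 33 genes called (0 adjusted over the list alone; median -0.28, adjusted p = 0.000992, adjusted p = 0.43 with an estimated correlation). The small RNA and chromatin list followed, with 0 of 38 genes higher and 1 lower (0 adjusted over the list alone; median -0.27, adjusted p = 0.0248, adjusted p = 0.311 with an estimated correlation), and lost its call without unpollinated ovary replicate 2 (-0.25). Among lists that did not pass, the abscisic acid list had 6 of 69 genes higher and 2 lower (10 and 3 adjusted over the list alone, adjusted p = 0.0814) and the MADS, HOX and YABBY list 5 of 60 higher and 1 lower (6 and 2 adjusted over the list alone; median -0.02, mean 0.24). HOX12 rose 33.6-fold and Hox22 9.02-fold. Sucrose and starch genes had 4 of 32 higher and 0 lower (5 and 2 adjusted over the list alone; median -0.01, mean 0.21, adjusted p = 0.144), with amy2A up at least 15.9-fold and the trehalose-phosphatase gene OsTPP9 5.2-fold. The auxin conjugating gene GH3.2 rose 13.4-fold.

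**Figure D3:**
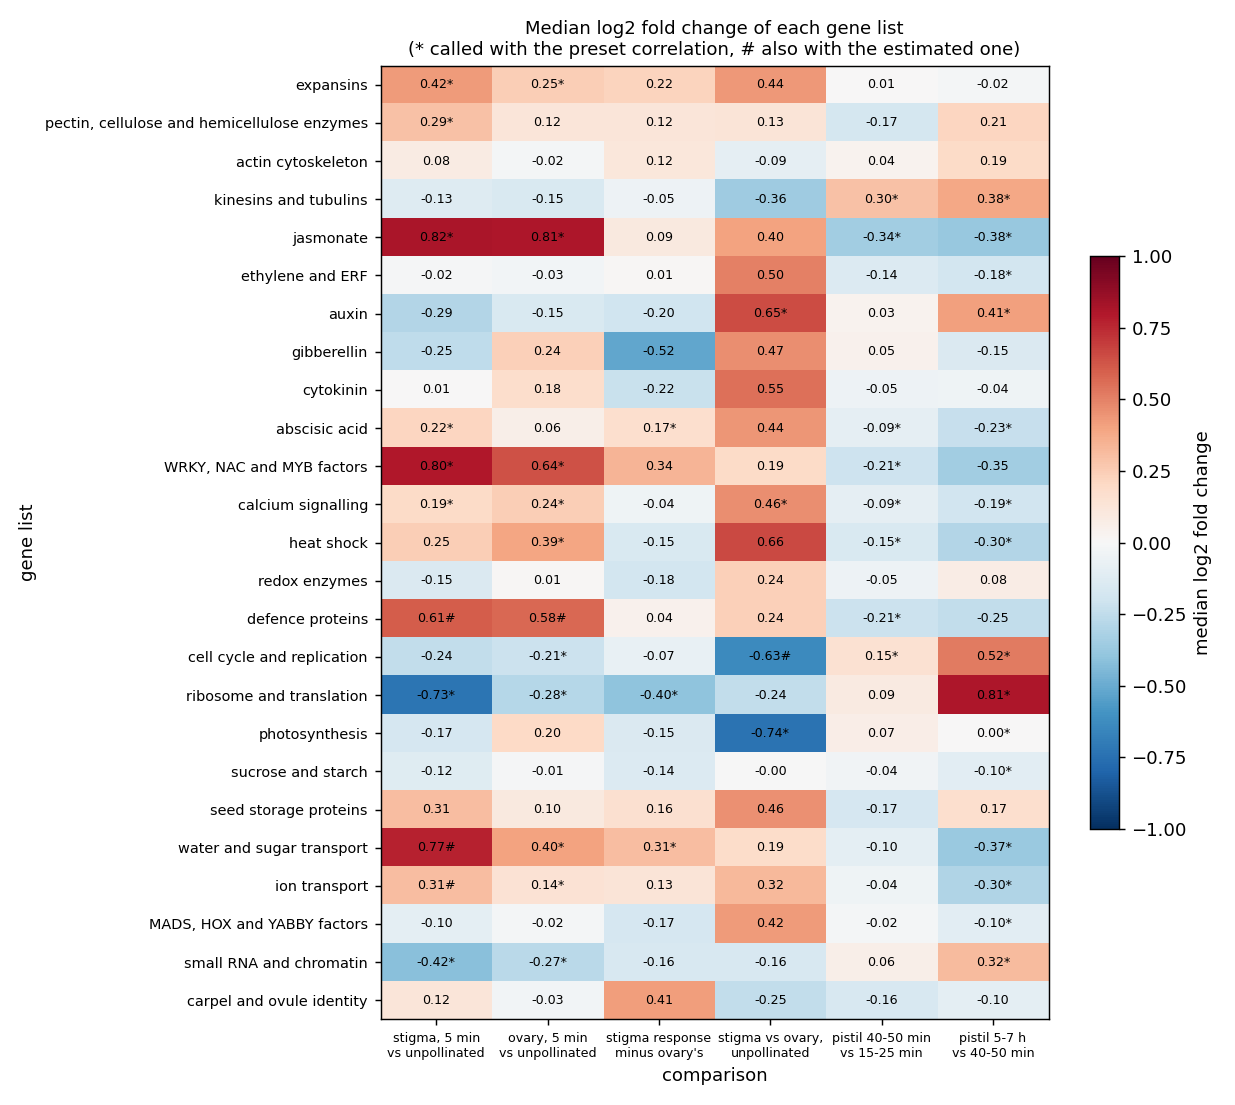
Median log2 fold change (colour) of 25 gene lists in 6 comparisons; * marks lists called with the preset correlation and # those also called with an estimated one. Defence proteins are called higher in both tissues at 5 min, and ribosome and translation genes shift from a median of -0.73 in the pollinated stigma to 0.81 in the pistil at 5 to 7 h against 40 to 50 min.

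Changes at 5 min in stigma and ovary were then set against each other. These comparisons share no arrays, but both, and the later one below, use 1 spread per probe set fitted over all arrays. Probe sets with little spread are thus called together more often, in whichever direction. The counts given for independent calls are therefore not a chance level. Higher in both tissues were 916 probe sets, where independent calls would give 118, and lower in both 393, where independent calls would give 96.0. Only 8 were higher in the stigma and lower in the ovary (61.6 if independent), and 9 the reverse (184 if independent). Across the 35470 probe sets, which are not independent replicates, the fold changes correlated at r = 0.698. The 916 shared genes had median log2 changes of 2.36 in the stigma and 1.73 in the ovary, and 76.7% changed more in the stigma. ML, ASMT, HOX12, the chitinase LOC4342115, EXPB9, EXP32, amy2A, OsSWEET5, CPK29, OsPht1;8 and YSL7 are named as higher in both tissues. Later, at 5 to 7 h against 40 to 50 min, 22.5% of the 916 fell (62.2 probe sets if independent) and 35 rose (103 if independent), while 126 of the 393 rose (44.1 if independent) and 35 fell (26.7 if independent).

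**Figure D4:**
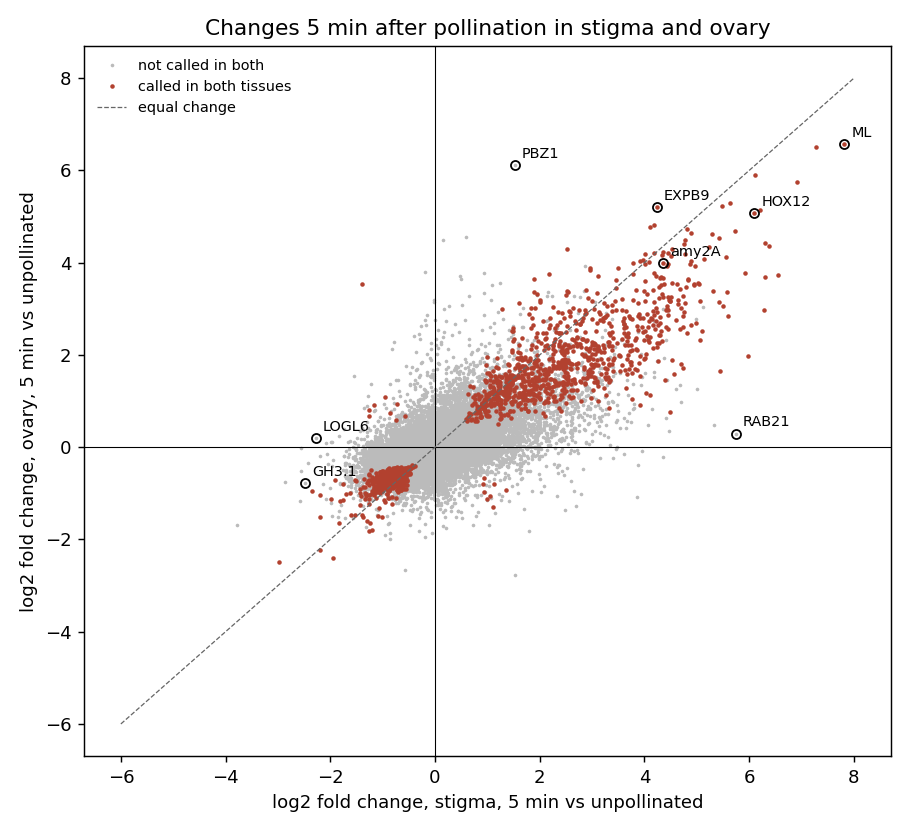
Log2 fold change at 5 min in the stigma (horizontal axis) against that in the ovary (vertical axis) for 35470 probe sets, with probe sets called in both tissues in red and a dashed line of equal change. ML, HOX12, EXPB9 and amy2A lie high in both tissues, RAB21 lies to the stigma side and PBZ1 to the ovary side.

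Whether the 5-min change itself differed between stigma and ovary was tested as an interaction, and 318 probe sets changed more upward in the stigma and 169 more upward in the ovary. A gene counted toward the ovary need not have risen there, as a fall in the stigma gives the same sign. RAB21, a dehydrin gene that responds to abscisic acid, rose in the stigma from 0.249 ± 0.0203 to 15.2 ± 10.4, while the ovary held 2.21 ± 1.92 and 2.16 ± 0.198, an interaction of 5.45 ± 0.92 (log2, SE). PSK4, which encodes a precursor of the peptide hormone phytosulfokine, went from 0.310 ± 0.0519 to 6.89 ± 0.873 in the stigma and from 0.363 ± 0.0172 to 0.637 ± 0.195 in the ovary (interaction 3.72 ± 0.31). OsUGE-1, a UDP-glucose epimerase gene, had an interaction of 3.80 ± 0.54, GLT2 of 3.33 ± 0.52 and the sugar exporter gene OsSWEET1b of 3.12 ± 0.56. PBZ1 went the other way (-4.59 ± 0.94), rising in the ovary as given above, from a level near the floor of 0.128. In the stigma its mean went from 1.34 ± 0.652 to 3.79 ± 1.83. The PBZ1 call ended without 5-min stigma replicate 1 (-4.08) or 5-min ovary replicate 3 (-4.31).

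By list, water and sugar transporters changed more upward in the stigma, with 2 of 36 genes higher and 0 lower (5 and 2 adjusted over the list alone, adjusted p = 0.00167, adjusted p = 0.563 with an estimated correlation). So did abscisic acid genes, with 2 of 69 higher and 0 lower (4 and 0 adjusted over the list alone, adjusted p = 0.0119, adjusted p = 0.563 with an estimated correlation), OsPP2C66 among them (2.01 ± 0.36). Ribosome genes changed more downward, with 0 of 33 called (0 adjusted over the list alone; median -0.40, adjusted p = 0.00167, adjusted p = 0.659 with an estimated correlation). The abscisic acid call ended without unpollinated stigma replicate 3 (median 0.17), unpollinated ovary replicate 1 (0.13) or 5-min stigma replicate 1 (-0.05, the opposite sign), and the ribosome call without 5-min stigma replicate 2 (-0.12). ARF15 (2.49 ± 0.37), GLU12 (2.78 ± 0.53), the actin gene ACT2 (1.64 ± 0.32) and the chitinase gene Cht6 (2.18 ± 0.34) were further interactions toward the stigma. For EXPB9 the interaction was -0.97 ± 1.08 and did not pass (adjusted p = 0.822). The number called, 487, was 260 without 5-min stigma replicate 2, 278 without 5-min ovary replicate 3, 738 without 5-min stigma replicate 1 and 876 without unpollinated stigma replicate 3. It was 174 with median centring, 147 with array weights, 78 when only the groups compared were fitted and 810 with a floor at the 40th percentile. Bright-probe scaling gave 555 toward the stigma and 117 toward the ovary and moved the median of all probe sets by 0.18.

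The unpollinated stigma and ovary were compared to ask which genes set the tissues apart before pollination. In the stigma CHS (LOC4350636), chalcone synthase of flavonoid synthesis, stood at 28.3 ± 18.5 against 0.231 ± 0.105 in the ovary (SD, n = 3 each), 104-fold higher. AT4 was 110-fold, the ABC transporter gene ABCG45 55.0-fold, the potassium transporter gene HAK20 52.6-fold, BHLH172 37.2-fold and LOGL6 at least 34.0-fold higher. Lower in the stigma were the germin-like GER3 (63.6-fold), the endoglucanase gene GLU5 (55.5-fold), OSH1, a meristem homeobox gene (20.7-fold), MADS29 (20.3-fold) and MAKIBA3 (20.3-fold). Among carpel and ovule identity genes, the ovule genes MADS21 and MADS13 and MADS6 were lower in the stigma (log2 -4.68 ± 0.35, -3.51 ± 0.31 and -2.55 ± 0.25, SE). MADS1, DL and MADS58 were higher (2.18, 1.74 and 0.61), and MADS3 did not pass (-0.25). All 3 arrays of one tissue lay beyond the 3 of the other for the genes ranked by size, as the rule for naming them required.

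Cell cycle and replication genes were lower in the stigma, with 7 of 62 higher and 36 lower (8 and 39 adjusted over the list alone, adjusted p = 7.74e-12), and the list kept its call, at adjusted p = 0.0334 with an estimated correlation. The replication licensing genes MCM2 and MCM3 were 18.2-fold and 15.3-fold lower. Of 17 photosynthesis genes 2 were higher and 9 lower (3 and 9 adjusted over the list alone, adjusted p = 0.00533, adjusted p = 0.533 with an estimated correlation), among them CHLH of chlorophyll synthesis (-3.49) and CAB2R (-3.24). Auxin genes were higher, 29 of 55 against 11 lower (30 and 11 adjusted over the list alone, adjusted p = 0.00533, adjusted p = 0.31 with an estimated correlation), with IAA12 (11.1-fold) and GH3.1 (10.4-fold). Calcium signalling genes were higher, 31 of 83 against 8 lower (34 and 9 adjusted over the list alone, adjusted p = 0.0174, adjusted p = 0.533 with an estimated correlation), with the kinases CIPK24 (13.2-fold) and CIPK17 (8.18-fold), and lost the call without unpollinated ovary replicate 3 (median 0.39).

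Of lists that did not pass between the unpollinated tissues, gibberellin had 7 of 14 genes higher and 1 lower, and cytokinin 14 of 30 higher and 3 lower (16 and 3 adjusted over the list alone), both at adjusted p = 0.0529. Expansins had 10 of 25 higher and 4 lower (11 and 4 adjusted over the list alone, adjusted p = 0.0713), led by EXP6 (19.3-fold), and EXPB9 was 11.1-fold higher. Abscisic acid genes had 28 of 69 higher and 6 lower (30 and 7 adjusted over the list alone, adjusted p = 0.0862). Single genes higher in the stigma were the oxidase gene OsrbohB (18.8-fold), sucrose synthase OsSUS3 (15.2-fold), the invertase CIN1 (12.4-fold), the aquaporin OsPIP1;3 (26.0-fold) and the salicylate-pathway gene NH3 (13.9-fold).

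The number of probe sets higher in the stigma was 6990 and lower 4643, with the median of all at 0.22. The balance turned with each other scaling: 5259 and 6404 after quantile normalization, 2650 and 6491 after median centring, and 3829 and 6635 with bright-probe scaling, which moved the median of all by -0.19, -0.32 and -0.20.

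The pistils at 40 to 50 min were set against those at 15 to 25 min, stages that the labels place at pollen tube growth and at fertilization. In limma 0 probe sets passed, the lowest adjusted p being 0.177. At an unadjusted p under 0.05 there were 451 higher and 582 lower, together fewer than chance alone gives on average among 35470 probe sets. In simulated data of this comparison 49 of 100 genes changed 2-fold and 94 of 100 changed 4-fold were recovered. By list, kinesins and tubulins shifted upward (median 0.30, adjusted p = 4.27e-07, adjusted p = 0.189 with an estimated correlation), as did cell cycle genes (median 0.15, adjusted p = 3.91e-06, adjusted p = 0.175 with an estimated correlation). Shifted downward were jasmonate (median -0.34, adjusted p = 0.000979, adjusted p = 0.374 with an estimated correlation), heat shock (-0.15, adjusted p = 0.0023, adjusted p = 0.423 with an estimated correlation), abscisic acid (-0.09, adjusted p = 0.00226, adjusted p = 0.374 with an estimated correlation), defence (-0.21, adjusted p = 0.00842, adjusted p = 0.189 with an estimated correlation), calcium (-0.09, adjusted p = 0.0114, adjusted p = 0.423 with an estimated correlation) and WRKY, NAC and MYB factors (-0.21, adjusted p = 0.0305, adjusted p = 0.423 with an estimated correlation). No gene of these lists passed on its own among all genes; adjusted over the list alone 1 gene of the WRKY, NAC and MYB list was higher and 0 of the other lists.

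Single arrays decide several list calls of this comparison, while the number of probe sets called changed little among 35470. Without 15 to 25 min replicate 2 that number was 6, without 15 to 25 min replicate 3 it was 4, and without 40 to 50 min replicate 3 it was 5. The calcium and heat shock calls ended without 15 to 25 min replicate 3 (medians -0.09 and -0.16) or 40 to 50 min replicate 3 (-0.09 and -0.11), the defence call without 40 to 50 min replicate 2 (-0.14), and the WRKY, NAC and MYB call without 15 to 25 min replicates 1 or 3 (-0.16 and -0.14) or 40 to 50 min replicates 2 or 3 (-0.16 and -0.29), and with a filter at the 75th percentile. Without 40 to 50 min replicate 3 the number of lists called fell from 8 to 5.

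At 5 to 7 h, the zygote stage in the labels, the pistils had more transcripts of division, translation and auxin genes than at 40 to 50 min, at the preset correlation only. With an estimated correlation the cell cycle, ribosome and auxin lists had adjusted p = 0.0802, adjusted p = 0.217 and adjusted p = 0.263. OsWRKY76 rose from 1.05 ± 0.273 to 12.1 ± 0.661 (SD, n = 3 each), a log2 change of 3.57 ± 0.37 (SE). The glutaredoxin gene GRXC3 rose 9.78-fold, the auxin response repressor IAA10 8.31-fold, CAD6 of lignin synthesis 7.96-fold, DAO, which oxidises auxin, 7.2-fold and FIB, of auxin synthesis, 6.73-fold. HOX12 fell 39.6-fold, from 10.6 ± 8.14 to 0.191 ± 0.0801, and ASMT fell at least 39.3-fold, with 2 of 3 arrays at the floor at 5 to 7 h. BURP17 fell at least 13.2-fold, the clock gene CCA1 11.1-fold and the aquaporin gene OsPIP2;4 9.28-fold. All 3 arrays of one stage lay beyond the 3 of the other for each, as the rule for naming them required.

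In total 3981 probe sets were higher and 2408 lower at 5 to 7 h, 1371 and 1118 of them by at least 2-fold. The 2 stages lie hours apart after pollination. Unless pollination was staggered, which is not given, hour of day and stage cannot be told apart in this comparison. After median centring, which moved the median of all by 0.13, 3427 were higher and 1155 lower.

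Of 62 cell cycle and replication genes 33 rose and 1 fell (34 and 4 adjusted over the list alone, adjusted p = 3.63e-10, adjusted p = 0.0802 with an estimated correlation). OsRPA70b, a subunit of a protein that binds single-stranded DNA, rose from 2.53 ± 0.442 to 15.1 ± 0.636, and MCM7 from 2.11 ± 0.241 to 10.2 ± 1.32. Of 33 ribosome and translation genes 26 rose and 0 fell (26 and 0 adjusted over the list alone, adjusted p = 4.47e-13, adjusted p = 0.217 with an estimated correlation), with RPS26 up 2.83-fold and RPL7A-2 2.28-fold. Of 43 kinesins and tubulins 14 rose and 0 fell (15 and 0 adjusted over the list alone, adjusted p = 0.0116, adjusted p = 0.324 with an estimated correlation), KIN14N by 2.73-fold. Of 38 small RNA and chromatin genes 12 rose and 1 fell (13 and 1 adjusted over the list alone, adjusted p = 0.00625, adjusted p = 0.241 with an estimated correlation), among them the DNA methyltransferase genes MET1 (LOC4342575; 4.31-fold) and CMT3 (4.16-fold). Of 55 auxin genes 16 rose and 4 fell (20 and 5 adjusted over the list alone, adjusted p = 0.0218, adjusted p = 0.263 with an estimated correlation), with IAA14 up 6.5-fold.

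Falls at 5 to 7 h took in several lists that had risen at 5 min. Of 69 abscisic acid genes 2 rose and 19 fell (3 and 21 adjusted over the list alone, adjusted p = 0.00192, adjusted p = 0.241 with an estimated correlation), with OsPP2C30 (-2.15) and PP2C68 (-2.09). Water and sugar transporters had 1 of 36 higher and 9 lower (1 and 10 adjusted over the list alone, adjusted p = 0.00745, adjusted p = 0.217 with an estimated correlation), including OsPIP2;5 (-2.59). Ion transporters had 4 of 66 higher and 9 lower (4 and 11 adjusted over the list alone, adjusted p = 0.0115, adjusted p = 0.185 with an estimated correlation), with the metal pump HMA2 (-1.76). Calcium signalling had 5 of 83 higher and 10 lower (5 and 10 adjusted over the list alone, adjusted p = 0.0198, adjusted p = 0.324 with an estimated correlation). Jasmonate genes had 1 of 31 higher and 3 lower (1 and 3 adjusted over the list alone, adjusted p = 0.0218, adjusted p = 0.324 with an estimated correlation), and heat shock genes 0 of 43 higher and 3 lower (0 and 2 adjusted over the list alone, adjusted p = 0.0102, adjusted p = 0.324 with an estimated correlation), among them hsp17.9 (-2.22). MADS, HOX and YABBY factors had 5 of 60 higher and 14 lower (6 and 14 adjusted over the list alone, adjusted p = 0.0178, adjusted p = 0.217 with an estimated correlation), HOX24 by -2.99. Photosynthesis genes had 1 of 17 higher and 8 lower (1 and 8 adjusted over the list alone; median 0.00, mean -0.64, adjusted p = 0.00552, adjusted p = 0.304 with an estimated correlation), with PORA (-2.39) and OsPSAG (-2.35). Sucrose and starch genes had 2 of 32 higher and 4 lower (2 and 6 adjusted over the list alone, adjusted p = 0.0218, adjusted p = 0.185 with an estimated correlation), AMY3D falling 4.93-fold and OsTPP4 4.75-fold. Ethylene genes had 0 of 17 higher and 4 lower (0 and 4 adjusted over the list alone, adjusted p = 0.0413, adjusted p = 0.185 with an estimated correlation), including ACO1 of ethylene synthesis (-2.63). The ethylene, calcium and sucrose calls ended without 40 to 50 min replicate 2 (medians -0.14, -0.17 and -0.10), and the ethylene call also without 40 to 50 min replicate 3 (-0.07) or 5 to 7 h replicate 3 (-0.16). The ethylene call also ended under quantile normalization, median centring and no filter, and the sucrose call with no filter.

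Whole pistils were last set against both unpollinated tissues, because a mixture of stigma and ovary lies between them; a gene was called only if it was higher than both or lower than both. At 15 to 25 min 1425 probe sets lay above both and 703 below. ML was 122-fold above whichever unpollinated tissue was nearer, ASMT 87.7-fold, the chitinase LOC4342115 83.5-fold, HOX12 53.0-fold and amy2A at least 39.9-fold. Above both were 12 of 69 abscisic acid genes (2 below), 12 of 83 calcium genes (0 below), 9 of 20 WRKY, NAC and MYB factors (0 below), 8 of 31 jasmonate genes (1 below) and 7 of 25 defence proteins (0 below). Median centring gave 1325 above and 111 below, bright-probe scaling 1632 and 351. The number called, 2128, was 1265 without 15 to 25 min replicate 3, 1333 without 15 to 25 min replicate 1 and 1392 without unpollinated ovary replicate 3.

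At 40 to 50 min 895 probe sets lay above both tissues and 514 below. ML was 63.6-fold, the chitinase LOC4342115 53.8-fold, amy2A at least 40.0-fold and MT1B 35.2-fold above the nearer tissue. Calcium signalling had 7 genes above and 0 below, jasmonate 6 above and 1 below, and defence proteins and WRKY, NAC and MYB factors 5 above and 0 below each. Median centring gave 808 above and 121 below, bright-probe scaling 1093 and 248. The number called, 1409, was 760 without 40 to 50 min replicate 1 and 830 without unpollinated ovary replicate 3.

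At 5 to 7 h 3055 probe sets lay above both tissues and 2628 below. OsWRKY76 was 73.4-fold, MT1B 60.8-fold, amy2A at least 38.1-fold and the chitinase LOC4342115 34.8-fold above the nearer tissue. CMT3 and OsRPA70b lay 8.6-fold and 8.02-fold above. Below both were OsTPP7 (log2 -3.96), CCA1 (-3.60), the expansin EXP1 (-3.35) and ACO1 (-3.32). Cell cycle genes had 27 of 62 above and 2 below, ribosome genes 20 of 33 above and 1 below, kinesins and tubulins 17 of 43 above and 1 below, auxin genes 9 of 55 above and 3 below, and abscisic acid genes 4 of 69 above and 13 below. MADS16, a stamen and lodicule identity gene, lay below both (-1.28). Median centring gave 2896 above and 1012 below.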

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

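None of the tests used here was chosen after its result was seen. The values listed are differences, on the log2 scale, between the response of the stigma and that of the ovary 5 min after pollination, and each was picked out because that tested difference passed. In all 487 probe sets did.

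Among the largest differences toward the stigma were RAB21 (5.45), RAB16B (3.99), OsUGE-1 (3.80), PSK4 (3.72), GLT2 (3.33) and OsSWEET1b (3.12). Wall and cytoskeleton genes toward the stigma were GLU12 (2.78), CSLD5 (2.04), ADF5 (2.04) and ACT2 (1.64). Signalling and defence genes on that side were ARF15 (2.49), OsPP2C66 (2.01), OsPP2C59 (1.97), Cht6 (2.18) and GRXC7 (1.62), and genes of sugar and transport were AMY3D (2.26), OsTIP2;1 (1.90) and YSL1 (1.52).

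Toward the ovary lay PBZ1 (-4.59), LOGL6 (-2.48), ABCG45 (-2.41), OsCASPL2C1 (-2.21), EXPB3 (-2.14) and PSK2 (-2.03). Smaller ones were LOGL5 (-1.94), EXLA4 (-1.73), OsrbohB (-1.60), CYCD5-1 (-1.56), MADS1 (-1.51), HAK25 (-1.22), ARF17 (-1.06) and ERS2 (-0.89). LOGL6 and CYCD5-1 fell in the stigma, as given above, so a place on this side does not mean a rise in the ovary. LOGL6 (at least 34.0-fold), ABCG45 (55.0-fold) and OsrbohB (18.8-fold) stood higher in the unpollinated stigma than in the ovary. For LOGL6 and OsTIP2;1 the floor sets part of the difference, as 2 of 3 unpollinated ovary arrays lie at it, and with no floor the values were -2.77 and 1.52, the latter not called.

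By list, abscisic acid genes differed by a median of 0.17, water and sugar transporters by 0.31 and ribosome and translation genes by -0.40. With an estimated correlation all 3 lists lost their call (adjusted p = 0.563, adjusted p = 0.563 and adjusted p = 0.659), and the abscisic acid median was -0.05 without 5-min stigma replicate 1.

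Leaving out single arrays ended part of these calls. RAB21, OsUGE-1, PSK4, GLT2, OsSWEET1b, GLU12, ACT2, ARF15, OsPP2C66 and Cht6 kept theirs with each array left out. The other genes named here lost theirs without at least 1 array, for example LOGL6 (-2.36) and AMY3D (2.13) without 5-min stigma replicate 2. That group then holds 1 array. The values lie near those from all arrays (-2.48 and 2.26), so the lost precision can end a call without the change resting on that array.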

How the results depend on the processing

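Scaling on always bright probe sets was chosen after array medians were seen; the other settings here were fixed before. Of 6486 values of named genes under other settings 5875 kept direction and call, 611 kept the direction without the call and 0 reversed. Calls were lost for 117 of 327 pairs of gene and comparison under some setting other than the 2-fold minimum. Of 680 values of called lists 592 kept their call, 88 lost it and 0 reversed the direction of the test, which compares a list with all genes. Of their medians 9 changed sign, 6 of them for photosynthesis at 5 to 7 h. For counts that moved, the cause was not tested, except that a 2-fold minimum can only lower them. The main fit gives each probe set 1 spread in all groups, but the groups differed in spread. Their median SD on the log2 scale was 0.27 in both stigma groups, 0.26 in the unpollinated ovary and 0.16 to 0.21 elsewhere. Calls that rest on the stigma groups may therefore be too many, which was not tested.

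For the stigma at 5 min (7810 called) median centring gave 5033, array weights 3252, fitting only the groups compared 1270, and a 2-fold minimum 3152. Leaving out single arrays gave 2968 to 8065.

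For the ovary at 5 min (2091) median centring gave 1120, no filter 1334, array weights 4215, fitting only the groups compared 867, and a 2-fold minimum 1233. Leaving out single arrays gave 787 to 2002.

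For the interaction (487) median centring gave 174, a floor at the 40th percentile 810, array weights 147, and fitting only the groups compared 78. Leaving out single arrays gave 260 to 876.

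For the unpollinated tissues (11633) fitting only the groups compared gave 5864 and a 2-fold minimum 5074. For pistils at 40 to 50 min against 15 to 25 min (0) a floor at the 40th percentile gave 2, array weights 2, and leaving out single arrays 0 to 6. For 5 to 7 h against 40 to 50 min (6389) array weights gave 10847 and a 2-fold minimum 2489.

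Against both unpollinated tissues, at 15 to 25 min (2128) fitting only the groups compared gave 1389, a 2-fold minimum 1114, and leaving out single arrays 1265 to 2255. At 40 to 50 min (1409) median centring gave 929, fitting only the groups compared 733, a 2-fold minimum 746, and leaving out single arrays 760 to 1481. At 5 to 7 h (5683) a 2-fold minimum gave 2316.

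Lists called numbered 11, 11, 3, 4, 8 and 15 in the first 6 comparisons, and 3, 1, 0, 1, 0 and 0 with an estimated correlation. Between the unpollinated tissues quantile normalization gave 7, median centring 8 and bright-probe scaling 8. Leaving out single arrays gave 7 to 13 in the stigma at 5 min and 5 to 11 at 40 to 50 min against 15 to 25 min.

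With the replicate number as a block the counts were 7999, 2254, 496, 12676, 0, 6984, 2262, 1543 and 5972. Of 57 pairs of arrays with the same number 22 correlated above 0.1 after group means were removed (mean r 0.0921, against -0.0459 for other numbers), and 13 of 20 arrays were closest to one of their own number, a hint of a shared effect. As not every pair passed 0.1, the numbers were not treated as paired.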

Other observations

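Genes that rose by 5 min followed different courses later. ML stood at 87.3 ± 16.2 (SD, n = 3) in pistils at 15 to 25 min, 55.9 ± 36.0 at 40 to 50 min and 17.0 ± 0.656 at 5 to 7 h. At 40 to 50 min replicate 2 stood at 16.0, and replicates 1 and 3 at 65.8 and 86.0, so its lower mean there comes from 1 array. ASMT, a methyltransferase of melatonin synthesis, went from 14.8 ± 0.602 through 9.03 ± 7.14 to 0.116 ± 0.0428. The metallothionein gene MT1B held 11.8 ± 1.37, 10.2 ± 4.41 and 16.7 ± 1.85, and the alpha-amylase gene amy2A 8.27 ± 2.61, 8.08 ± 1.13 and 7.69 ± 1.12. The expansin EXPB9, at 64.3 ± 2.51 in the stigma and 12.3 ± 6.32 in the ovary at 5 min, was 5.84 ± 4.44, 12.1 ± 9.47 and 11.5 ± 1.56 in the pistils.

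The replication gene MCM2 stood at 4.35 ± 1.26 in the unpollinated ovary and 18.3 ± 1.75 in pistils at 5 to 7 h (SD, n = 3 each). MADS29, a B-sister MADS gene of the nucellus, stood at 2.96 ± 0.392 and 7.81 ± 0.434, and its call above both unpollinated tissues ended without several single arrays (log2 1.41, and 1.32 without unpollinated ovary replicate 3). CHS, chalcone synthase, stood at 28.3 ± 18.5 in the unpollinated stigma, 0.231 ± 0.105 in the unpollinated ovary and 0.349 ± 0.133 in those pistils.

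The tests of scaling for all falls and for the size of the falls of at least 2-fold, of dilution, of stigma carry-over, of pollen in both samples and of the clock genes were chosen only after the results were seen; the tests of how many falls of at least 2-fold stay called under other scalings and of regrouped arrays were not.

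In the stigma at 5 min 4756 probe sets were lower, most by less than 2-fold. A shift in the reference that each array is scaled to could give many of them, since the number lower under other scalings ran from 1831 to 5604. Of the 798 falls of at least 2-fold, 84.8% were called lower under every scaling, against 25.5% of the smaller falls. Over 90% had been set beforehand as the bound against scaling, and it was not met. Larger falls stay called more often under any small shift, so the contrast with the smaller ones does not decide on scaling. Their median of -1.16 was -0.93 (SE 0.25) under the scaling that left them smallest. They were picked for their size under the main scaling, so this value mostly returns the shift of the other scaling. It shows only that the references tried here moved them by less than their size. Whether a reference gave these falls stays open. Dilution of stigma RNA by pollen RNA stays open as well. Of all the falls 45.0% lie below the median change of 103 probe sets preferring the stigma (-0.15, 10 of them lower) at adjusted p under 0.05. These 103 were picked against the ovary and not shown to be absent from pollen or unmoved by pollination. The falls were themselves picked as lower, so this test cannot decide on dilution.

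The 916 probe sets higher in both tissues could come from pollen in both samples, from stigma tissue carried into the ovary samples, or from a response of each tissue. Some carry-over may be present, as 56 of 103 probe sets preferring the stigma rose in the ovary, where these 103 gained a median of 5.80% of their stigma level. The 916 gained a median of 32.7%, on the 3 ovary arrays 1.04 to 2.99 times the share that 9 in 10 of the 103 keep under. The 916 were picked for a rise in the ovary and the 103 were not, which raises that ratio. The ratio alone cannot decide on carry-over. On ovary replicates 1, 2 and 3 the 103 gained medians of 2.85%, 10.97% and 3.02%, and the 916 gained 31.6%, 21.5% and 42.6%. The 916 gained least where the 103 gained most, the reverse of what carry-over gives. Picking for a rise does not set that order. These values argue against carry-over as the main source of the gain of the 916 as a set. They do not exclude it for single genes. For pollen, the Spearman rho of the ratios of ovary to stigma gain between disjoint sets of arrays had a median of 0.495 over 216 choices of arrays (-0.117 to 0.726), so the arrays chosen decide it and pollen stays open.

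The tests of that pattern were revised after their outcomes were seen. The ones first used compared each gene with a bound of 2 standard errors: 32.0% of the 916 lay over the share of stigma-preferring genes and 8.84% over 2 times the ratio of EXPB9. They were replaced because 2 or 3 arrays were judged to give them little power, which was not measured. The bound for carry-over was then moved from 1 to 1.5 after the value of 1.04 was known, which changed the outcome from excluded to open. The rho, chosen after an earlier test of the pollen explanation, was first taken between replicates 1 and replicates 2 alone (-0.0344, 914 genes), and was widened to every choice of arrays after that value was known. This changed the outcome from fitting pollen to open, so the outcomes of the ratio and of the rho may lean on those choices and carry little weight. The shares on single ovary arrays were also compared after these outcomes were known, but that comparison uses no bound.

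Clock genes changed as well, and the hour of collection may explain part of 2 comparisons. At 5 to 7 h 4 of 7 clock genes differed from 40 to 50 min toward a later hour and 0 against (CCA1 -3.47, PRR73 -0.68, PRR1 1.59 and PCL1 2.69; 3 or 4 with single arrays left out). In the stigma at 5 min 3 of 7 differed toward an earlier hour and 0 against (PRR95 -1.40, PRR1 -1.97 and PCL1 -2.55), with 2 left without unpollinated stigma replicate 2 and 0 without 5-min stigma replicate 2 (PRR95 -1.11, PRR1 -1.48 and PCL1 -2.13 there). In the ovary 1 of 7 did (PRR95 -1.47), a call that ended without any of 5 single arrays, at -1.09 to -1.55. The hour of collection is not given in the sources used here. Pistils at 5 to 7 h and at 40 to 50 min lie hours apart after pollination. Unless pollination was staggered, hour of day and stage cannot be told apart there. CCA1 varied within the unpollinated groups (16.4 ± 12.2 in the stigma, against 11.4 ± 0.790 at 5 min), and a response of the clock genes to pollination stays open.

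Arrays were also regrouped within comparisons, keeping the group sizes, and for 2 groups of 3 in every way. In the ovary at 5 min 1 of 10 groupings, the real one, gave as many probe sets (2091, highest other 0) and as many lists (11, highest other 10). Between the unpollinated tissues 1 of 10 groupings did for probe sets (11633, highest other 420) and 6 of 10 for lists (4, highest other 10). For pistils at 40 to 50 min against 15 to 25 min all 10 of 10 gave as many probe sets as the real 0, the highest being 158, and 1 of 10 as many lists (8, highest other 4). That 158 came from 15 to 25 min replicate 1 with 40 to 50 min replicates 1 and 2, which points to a structure of the samples. At 5 to 7 h against 40 to 50 min 1 of 10 did for probe sets (6389, highest other 0) and 1 of 10 for lists (15, highest other 13). With 10 groupings no share can fall under 0.05. In the ovary, between the unpollinated tissues and at 5 to 7 h, mixed groupings gave nearly as many lists as the real one or more. Mixed groupings keep part of a real difference. Even so, a list call at the preset correlation alone carries little weight here, whatever its adjusted p.

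Against both unpollinated tissues 100 of the 840 possible groupings were drawn for each stage, the real one included. At 15 to 25 min 1 of 100 gave as many (2128, highest other 1215), at 40 to 50 min 4 of 100 (1409, highest other 6791) and at 5 to 7 h 3 of 100 (5683, highest other 8279). The counts of 6791 and 8279 came when the 3 unpollinated stigma arrays took the place of the pistils, which points to the difference between stigma and the other samples as a structure of its own. Groups of 2 arrays were not regrouped.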
